A study of Mus musculus with 18 samples.

How the data were processed

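Gene expression was measured in 3T3-L1 cells, a mouse preadipocyte line that turns into adipocytes in culture. Per the labels' protocols, cells were differentiated for 7 days and then treated for 24 hours with DMSO (the vehicle), 100 nM rosiglitazone, 25 µM sodium diclofenac, 10 µM indomethacin, 75 µM ibuprofen or 10 µM GQ16. Each of the 6 groups had 3 samples, and each sample was hybridised to 1 array, for 18 Illumina mouse BeadChip arrays in all. The labels do not state whether the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

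The values used are the authors' processed intensities as deposited, on a log2 scale, 1 value per probe and array. GenomeStudio and lumi are named in the submitters' processing notes, and the version, order and settings of each are not given in the sources used here. All 18 columns held the same set of sorted values, so the authors had made the arrays' distributions identical (quantile normalization). Every array had a lowest value of 5.68, a lower quartile of 5.75, a median of 5.98 and a highest value of 14.8. Base 2 was inferred from the highest value, which would lie outside a scanner's range with another base. Probes were not centred. Whether a background adjustment or a variance-stabilising transform preceded the normalization stays unknown. Dim probes were compressed toward the floor, so fold changes of weakly expressed genes are understated. Equal distributions also hide any change that shifts most transcripts one way. A table of non-normalized signals was not used here, because the names of its 36 columns of values per sample could not be matched to samples. The background correction planned on those signals (limma's neqc) and the planned filter on detection p-values therefore could not be run, and the deposited values took their place.

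Of the 45281 probes, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 had none. Symbols were checked by Entrez identifier against a RefSeq gene table (assembly GRCm38.p6), which matched 34807 probes and changed 0 symbols. The annotation's genome build is not given in the sources used here, so no coordinates are reported. A probe counted as above background on an array when its value exceeded 6.18, the 95th percentile of the 1526 probes for olfactory, vomeronasal and trace amine receptors, genes taken as silent in adipocytes. This filter replaced the planned one after the files had been seen. Probes above that level on at least 3 arrays were kept, 21132 in all, of which 17674 had 1 symbol. On each array 42.1% of probes (19069) were above background. Where a gene had several such probes, the one with the highest mean over the 18 arrays stood for it, which left 10958 genes. Where a gene's values were below background on all 3 arrays of 1 group, its fold change is a bound, computed against the background level and given as "at least".

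Genes were tested with limma 3.58.1 in R 4.3.3. A single fit over the 18 arrays had 1 mean per group, with 12 residual degrees of freedom, an intensity trend in the variance prior and 11.9 prior degrees of freedom. An F test asked which genes differed among the 6 groups. Moderated two-sided tests compared each of the 5 compounds with DMSO, and 7 more compared the other 4 compounds with rosiglitazone and the 3 non-steroidal anti-inflammatory drugs with one another. Adjusted p-values are Benjamini-Hochberg values over all genes tested within a comparison, and a gene was called, and is said to have risen or fallen, at an adjusted p under 0.05. Log2 changes are given with the fit's standard error (SE) or a 95% confidence interval, and levels with the standard deviation (SD).

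The design, the gene lists, the rule for named genes and most of the other settings tried were fixed before the data were examined. The 21 lists held 474 entries: PPARγ target genes, adipocyte differentiation, adipokines and insulin signalling, genes linked to phosphorylation of PPARγ by Cdk5, thermogenic genes, fatty acid oxidation, fatty acid and triglyceride synthesis, cholesterol synthesis, oxidative phosphorylation, glycolysis and hypoxia, inflammatory genes, interferon response, the prostaglandin pathway, amino acid stress (ATF4) genes, endoplasmic reticulum (ER) chaperones, oxidative stress and xenobiotic genes, extracellular matrix, preadipocyte and fibroblast markers, cell cycle, ribosomal proteins and macrophage markers. Some genes stand in several lists, and 336 list genes were measured. Lists with at least 5 measured members were tested, which took in 20; the macrophage list had fewer. Each was set against all other genes with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 20 lists of a comparison. Camera with the correlation estimated from the data is given beside each list that passed. Limma's fry, which asks whether a list's genes move one way on balance without reference to other genes, served as a further alternative. Counts "adjusted over the list alone" use Benjamini-Hochberg values within that list.

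Named genes followed the fixed rule. Against DMSO these were the 10 largest rises and 10 largest falls among called genes whose 3 treated arrays all lay on one side of the 3 DMSO arrays, up to 4 called members of each list with the largest change, and a panel of 13 genes named whatever their result (Pparg, Fabp4, Cd36, Adipoq, Pdk4, Angptl4, Plin2, Cidec, Fgf21, Ucp1, Retn, Ptgs1 and Ptgs2). Comparisons with fewer than 5 called genes name all of these and the 5 of lowest p. Between compounds the 5 largest rises and 5 largest falls among called genes and the panel were named. Unnamed RIKEN or locus symbols counted toward these numbers and were left out of the text. Genes outside the rule are said to have been chosen after their values were seen. Agreement with rosiglitazone was described by correlations and covariances of log2 changes across genes, which are not independent replicates. Because all comparisons share the 3 DMSO arrays, each value is set beside 100 simulations of unchanged groups against the same controls, and beside 100 regroupings of the residuals of the 18 arrays, added after the data had been seen. The 3 DMSO arrays are too few to split.

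The labels place the arrays on 3 slides. Slide 1 held DMSO replicates 1 and 2, rosiglitazone replicates 2 and 3, diclofenac replicate 2 and indomethacin replicate 3. On slide 2 were DMSO replicate 3, the 3 ibuprofen arrays, GQ16 replicate 1 and diclofenac replicate 1. Rosiglitazone replicate 1, diclofenac replicate 3, indomethacin replicates 1 and 2 and GQ16 replicates 2 and 3 lay on slide 3, which held no DMSO array. Values with slide as a block and within each slide that held both groups stand beside the results.

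Alternatives were no filter on dim probes, slide as a fixed or random block, the replicate number as a block, all probes in place of 1 per gene, no intensity trend, array weights, only the 2 groups compared in the fit, only 1 slide, each array left out in turn, the estimated correlation and fry for lists, and Spearman correlation or only genes called for rosiglitazone for the similarity of compounds. Alternatives added after the data had been seen were a stricter filter (above 6.52, the 99th percentile of the same receptor probes, on all 3 arrays of a group), arrays shifted to one median, cyclic loess, gene-by-gene array weights, and a fit without rosiglitazone replicate 1 and DMSO replicate 3.

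The procedure was tested on simulated data for rosiglitazone against DMSO over 10958 genes, of which 200 were changed. It recovered 46.5% of changes of 0.5 on the log2 scale, 97% of changes of 1 and 100% of changes of 2, with 5.10%, 4.43% and 5.66% of the calls false. It made 0 limma calls in an unchanged comparison, and a list shifted by 0.3 was called while 0 of the 19 other lists were. Correlated genes and arrays were not simulated, so real error rates may differ.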

Results

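Transcript levels were compared in 3T3-L1 adipocytes after 24 hours with the vehicle DMSO, with rosiglitazone, with 1 of 3 non-steroidal anti-inflammatory drugs (diclofenac, indomethacin and ibuprofen) or with the compound GQ16. Rosiglitazone is a thiazolidinedione that activates PPARγ, the nuclear receptor that drives adipocyte differentiation. The series title asks how these drugs and GQ16 activate PPARγ, and each compound was therefore set against DMSO and against rosiglitazone. The concentrations differed: 100 nM rosiglitazone, 25 µM diclofenac, 10 µM indomethacin, 75 µM ibuprofen and 10 µM GQ16. Each group had 3 arrays, and on every array 42.1% of the 45281 probes lay above background. Among the 10958 genes tested, 2026 differed among the 6 groups (limma F test).

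Rosiglitazone replicate 1, on slide 3, lay farthest from its group (root mean square deviation 0.286 on the log2 scale, against 0.229 and 0.156 for rosiglitazone replicates 2 and 3). DMSO replicate 3, the vehicle array on slide 2, deviated by 0.207, against 0.120 and 0.136 for DMSO replicates 1 and 2. Slide 2 held only this DMSO array and slide 3 only this rosiglitazone array, so values within those slides rest on 1 array of that group. Counts without these 2 arrays, called the 2 arrays apart, stand beside the comparisons; that alternative was added after the data had been seen.

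Rosiglitazone raised 883 genes and lowered 1101 (1104 and 942 with arrays shifted to one median, so the balance depends on scaling). Acaa1b, a peroxisomal 3-ketoacyl-CoA thiolase, rose by 3.96 ± 0.16 on the log2 scale (SE, n = 3 per group, adjusted p = 2.12e-14), with 3.92 blocked and 3.95 within slide 1 (blocked values come from a fit with slide as a block). The fatty acid elongase Elovl3 rose by 2.55 ± 0.18 and the secreted metabolic hormone Fgf21 by 2.44 ± 0.17. The keratin Krt23 rose by 2.13 ± 0.17 and the chemokine Cxcl1 by 2.11 ± 0.19. Among the falls, Orm2, an orosomucoid of the acute-phase response, changed by -2.34 ± 0.14 (adjusted p = 5.06e-11), with -2.39 blocked and -2.35 within slide 1; the EGF receptor inhibitor Errfi1 changed by -2.03 ± 0.14 and the adhesion molecule Vcam1 by -1.62 ± 0.15. Probes of Acaa1b and Orm2 may also bind the transcripts of their close relatives Acaa1a and Orm1. Over 2-fold rises and falls numbered 79 and 132, against 6 and 12 with diclofenac, 36 and 75 with indomethacin, 30 and 56 with ibuprofen and 1 and 4 with GQ16.

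**Figure D1:**
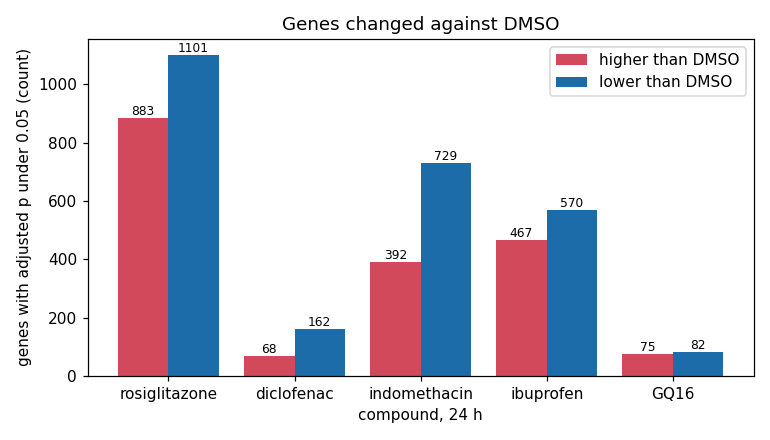
Bars give the number of genes with a limma adjusted p under 0.05 that were higher or lower than with DMSO for each compound after 24 hours (3 arrays per group, no error bars). Rosiglitazone changed 883 and 1101 genes, and GQ16 changed 75 and 82.

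Of 23 measured PPARγ target genes, 9 rose with rosiglitazone and 14 did not pass (10 rose adjusted over the list alone). Besides Fgf21 these included the glycerol channel Aqp7 (1.23 ± 0.19), the glycerol-3-phosphate dehydrogenase Gpd1 (1.17 ± 0.19), the lipid droplet coat protein Plin2 (0.71 ± 0.17) and the lipoprotein lipase inhibitor Angptl4 (0.70 ± 0.12). The list's median was 0.26, or 0.27 blocked, 0.33 within slide 1 (camera adjusted p = 8.24e-07, 0.00115 with an estimated correlation, range 1.12e-08 to 0.00115; ranges of a list's adjusted p are over its 20 alternatives). Fabp4, the fatty acid binding protein of adipocytes, did not pass at 0.63 (adjusted p = 0.0997), nor did the adipokine Adipoq at 0.17, Cidec at 0.26, Pdk4 at 0.16 or Retn at -0.13. Cd36 rose by 0.61, a call lost without DMSO replicate 1 or 2 or rosiglitazone replicate 1 (adjusted p up to 0.0974). Pparg itself fell by 0.76 from 13.84 ± 0.16 to 13.08 ± 0.20 (SD, normalized log2 intensity, adjusted p = 8.32e-05). Ucp1 and Ptgs2 were above background on 0 arrays, and Ptgs1 had no probe with its symbol.

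Mitochondrial and oxidative genes were higher with rosiglitazone as lists, by camera at its preset correlation but not with an estimated one. In the fatty acid oxidation list the β-oxidation enzyme Decr1 (1.44 ± 0.17) and Etfdh (0.66 ± 0.14) rose. In all, 7 of its 21 genes rose and 14 did not pass (7 rose adjusted over the list alone). Its median was 0.20, or 0.26 blocked, 0.33 within slide 1 (camera adjusted p = 0.000312, 0.0875 with an estimated correlation, range 3.08e-06 to 0.0875). Of 30 oxidative phosphorylation genes 6 rose (7 adjusted over the list alone), including the complex I subunit Ndufb3 (0.58). The median was 0.21, or 0.18 blocked, 0.15 within slide 1 (camera adjusted p = 0.00148, 0.102 with an estimated correlation, range 0.000143 to 0.102). In the thermogenic list 3 of 10 rose (4 rose and 1 fell adjusted over the list alone), with Elovl3 and the coactivator Ppargc1a (0.94 ± 0.17) leading. That list's median was 0.13, or 0.10 blocked, 0.20 within slide 1 (camera adjusted p = 0.0143, 0.0982 with an estimated correlation, range 7.9e-05 to 0.0982). The cell cycle list had 10 rises among 19 genes (11 adjusted over the list alone). The median was 0.35, or 0.33 blocked, 0.26 within slide 1 (camera adjusted p = 0.000684, 0.113 with an estimated correlation, range 9.26e-05 to 0.113).

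Matrix and fibroblast genes were lower as lists by camera at its preset correlation, and only the matrix list also passed with an estimated one. Of 20 extracellular matrix genes 11 fell and 9 did not pass (12 fell and 1 rose adjusted over the list alone), among them the collagen cross-linking enzyme Lox (-1.57 ± 0.14) and fibronectin, Fn1 (-1.33 ± 0.21). The median was -0.36, or -0.34 blocked, -0.35 within slide 1 (camera adjusted p = 8.24e-07, 0.0222 with an estimated correlation, range 1.12e-08 to 0.0222). Among 20 preadipocyte and fibroblast markers 9 fell (10 fell and 1 rose adjusted over the list alone), such as Tgfbi (-1.61 ± 0.17) and Gas6 (-1.01). The median was -0.36, or -0.38 blocked, -0.42 within slide 1 (camera adjusted p = 0.000806, 0.0982 with an estimated correlation, range 3.19e-05 to 0.0982). Inflammatory genes went down, with 7 falls, including Lcn2 (-0.81) and Serpina3n (-0.78), and 1 rise, Cxcl1, among 15 (9 and 1 adjusted over the list alone). Their median was -0.40, or -0.41 blocked, -0.40 within slide 1 (camera adjusted p = 0.00891, 0.0869 with an estimated correlation, range 4.58e-05 to 0.0869). Of 15 interferon response genes 6 fell and 1 rose (7 and 1 adjusted over the list alone), with Irf7 at -0.60 (above background on 1 of 3 rosiglitazone arrays). The median was -0.29, or -0.32 blocked, -0.34 within slide 1 (camera adjusted p = 0.00543, 0.264 with an estimated correlation, range 0.000463 to 0.264).

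The remaining lists did not pass with rosiglitazone. Fatty acid and triglyceride synthesis had 2 rises and 5 falls among 20 genes (2 and 6 adjusted over the list alone, camera adjusted p = 0.0693), and the lipogenic genes Mlxipl (-0.98), Thrsp (-0.92) and Dgat2 (-0.52) fell. Amino acid stress genes had 6 rises and 2 falls among 19 (adjusted p = 0.243). Oxidative stress and xenobiotic genes had 2 and 5 (of 19, adjusted p = 0.674). Adipokines and insulin signalling had 2 and 5 (of 15, adjusted p = 0.303), with the insulin receptor substrate Irs2 at 1.15 and the glucose transporter Slc2a4 at -0.69. Adipocyte differentiation had 2 and 3 (of 18, adjusted p = 0.792), Cdk5-linked genes 1 and 3 (of 12, 0.425), cholesterol synthesis 2 and 4 (of 18, 0.674), and glycolysis and hypoxia 1 and 3 (of 18, 0.792). The prostaglandin pathway had 1 and 2 (of 10, 0.792), ER chaperones 1 rise among 15 (0.425), and ribosomal proteins 0 limma calls among 18 (2 higher and 2 lower at an unadjusted p under 0.05, 0.792). Median, mean and test differed in sign for the prostaglandin, oxidative stress and ribosomal lists.

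Of the 86 called genes named for rosiglitazone, 85 were called with slide as a block and 64 whichever array was left out. Direction within slides is no check on slide, as the genes were chosen from the same arrays. With the block 1959 genes were called in all, against 2283 on slide 1 alone and 1956 without the 2 arrays apart. Leaving out DMSO replicate 1 or 2 gave 1204 or 1198 genes.

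**Figure D2:**
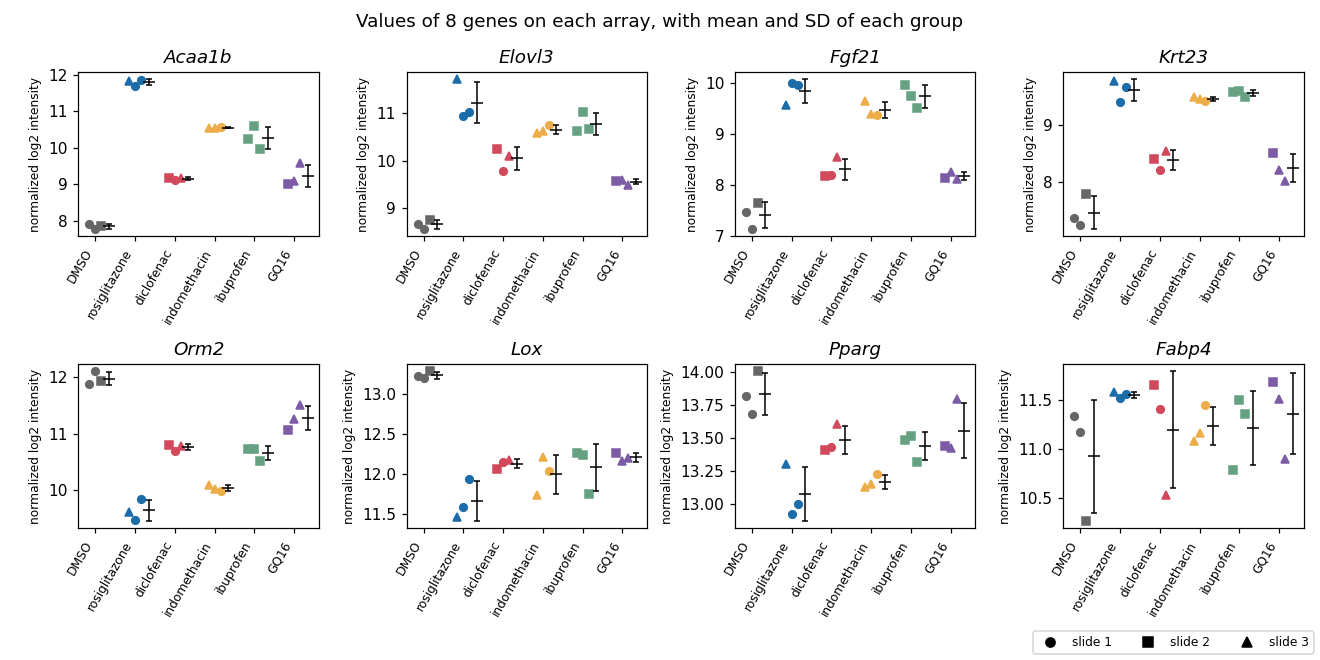
Normalized log2 intensity of 8 genes on each of the 18 arrays, by group, with the marker shape giving the slide and the bar beside each group its mean and SD (n = 3). The genes were picked for display after their values were seen, except for Pparg and Fabp4 of the fixed panel; Acaa1b rose by 3.96 with rosiglitazone and 1.31 with diclofenac.

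Diclofenac raised 68 genes and lowered 162. Elovl3 rose by 1.38 ± 0.18 (SE, n = 3 per group, adjusted p = 6.37e-05), with 1.29 blocked and 1.17 and 1.49 within slides 1 and 2, and Acaa1b by 1.31 ± 0.16 (adjusted p = 4.78e-05). Orm2 changed by -1.22 ± 0.14, with -1.24 blocked and -1.30 and -1.15 within slides 1 and 2, and Errfi1 by -1.20 ± 0.14. Lower too were the phosphorylase kinase subunit Phkg1 (-1.12 ± 0.15), Vcam1 (-1.09 ± 0.15) and the lipogenic gene Thrsp (-0.83 ± 0.13).

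Among 23 PPARγ targets 1 rose with diclofenac and 22 did not pass (3 rose adjusted over the list alone), yet the list as a whole was higher. The median was 0.15, or 0.17 blocked, 0.21 and 0.15 within slides 1 and 2 (camera adjusted p = 0.000372, 0.0158 with an estimated correlation, range 7.47e-05 to 0.0158). The called member was Fgf21 at 0.89 ± 0.17, a call lost without DMSO replicate 2 (adjusted p = 0.0517). Angptl4 at 0.42 (adjusted p = 0.0589), Fabp4 at 0.27, Cd36 at 0.15, Plin2 at 0.30 and Pparg at -0.35 (adjusted p = 0.143) did not pass. The cell cycle list was higher, with 2 rises among 19 (7 adjusted over the list alone), such as the replication licensing factor Mcm5 (0.74 ± 0.15). The median was 0.27, or 0.27 blocked, 0.23 and 0.35 within slides 1 and 2 (camera adjusted p = 7.42e-06, 0.0899 with an estimated correlation, range 1.3e-06 to 0.0899). Oxidative phosphorylation had 0 limma calls among 30 genes (5 higher and 0 lower at an unadjusted p under 0.05). The median was 0.13, or 0.17 blocked, 0.13 and 0.24 within slides 1 and 2 (camera adjusted p = 0.00138, 0.151 with an estimated correlation, range 7.06e-05 to 0.196). The call was lost without DMSO replicate 3 (adjusted p = 0.159).

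Extracellular matrix genes were lower, with 2 falls among 20 (7 fell and 1 rose adjusted over the list alone), Lox at -1.10 ± 0.14 among them. The median was -0.24, or -0.21 blocked, -0.25 and -0.11 within slides 1 and 2 (camera adjusted p = 1.91e-05, 0.0491 with an estimated correlation, range 6.27e-06 to 0.0491). Of 20 preadipocyte and fibroblast markers 2 fell (3 adjusted over the list alone), Tgfbi at -0.91 ± 0.17 among them. Their median was -0.16, or -0.19 blocked, -0.32 and 0.04 within slides 1 and 2, so it changed sign on slide 2 (camera adjusted p = 0.000372, 0.109 with an estimated correlation, range 3.57e-05 to 0.109). The other 15 lists did not pass, with the lowest camera adjusted p for fatty acid oxidation (0.0559); median, mean and test differed in sign for adipocyte differentiation, Cdk5-linked genes and glycolysis and hypoxia. Of the 37 called genes named for diclofenac, 35 were called with slide as a block and 20 whichever array was left out. The count of 230 genes came to 278 with the block and 487 without the 2 arrays apart, and to 100 or 118 without DMSO replicate 1 or 2 and 117, 93 or 127 without diclofenac replicate 1, 2 or 3.

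Indomethacin raised 392 genes and lowered 729. Acaa1b rose by 2.72 ± 0.16 (SE, n = 3 per group, adjusted p = 1.07e-10), with 2.65 blocked and 2.75 within slide 1, and Fgf21, Elovl3 and Krt23 by 2.06 ± 0.17, 1.99 ± 0.18 and 1.97 ± 0.17. Orm2 changed by -1.95 ± 0.14 (adjusted p = 2.67e-09), with -2.02 blocked and -2.02 within slide 1, and Phkg1 by -1.46 ± 0.15.

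Of 23 PPARγ targets 3 rose with indomethacin, namely Fgf21, Plin2 (0.85 ± 0.17) and Angptl4 (0.67 ± 0.12), and 20 did not pass (6 rose adjusted over the list alone). Their median was 0.25, or 0.28 blocked, 0.21 within slide 1 (camera adjusted p = 2.28e-05, 0.00428 with an estimated correlation, range 4.12e-07 to 0.00428). Pparg fell from 13.84 ± 0.16 to 13.17 ± 0.05 (SD, normalized log2 intensity, log2 change -0.67, adjusted p = 0.00062), while Fabp4 at 0.31 (adjusted p = 0.523) and Cd36 at 0.25 did not pass. In the fatty acid oxidation list 2 of 21 rose (2 adjusted over the list alone), with Decr1 at 0.89 ± 0.17. The median was 0.17, or 0.23 blocked, 0.21 within slide 1 (camera adjusted p = 0.00306, 0.113 with an estimated correlation, range 0.000192 to 0.113). Oxidative phosphorylation had 3 rises among 30 (4 adjusted over the list alone). The median was 0.17, or 0.19 blocked, 0.11 within slide 1 (camera adjusted p = 0.000434, 0.082 with an estimated correlation, range 2.29e-05 to 0.082). Amino acid stress genes were higher, with 3 rises and 1 fall among 19 (5 and 1 adjusted over the list alone). The cystine transporter Slc7a11 (0.94 ± 0.14) led them, and their median was 0.27, or 0.22 blocked, 0.10 within slide 1 (camera adjusted p = 0.00306, 0.082 with an estimated correlation, range 0.000894 to 0.082).

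Of 20 extracellular matrix genes 11 fell with indomethacin (13 adjusted over the list alone), among them Lox (-1.23 ± 0.14), Fn1 (-1.21 ± 0.21) and the collagen gene Col1a1 (-1.07 ± 0.18). Its median was -0.47, or -0.39 blocked, -0.47 within slide 1 (camera adjusted p = 2.79e-09, 0.00576 with an estimated correlation, range 4.7e-12 to 0.00576). Of 20 preadipocyte and fibroblast markers 7 fell (9 fell and 1 rose adjusted over the list alone), such as Tgfbi (-1.10) and decorin, Dcn (-0.79). The median was -0.30, or -0.22 blocked, -0.33 within slide 1 (camera adjusted p = 0.000434, 0.082 with an estimated correlation, range 0.000102 to 0.082). Interferon response genes had 4 falls and 1 rise among 15 (7 and 1 adjusted over the list alone), with Irf7, below background on all indomethacin arrays, at least 1.41-fold lower. The median was -0.29, or -0.48 blocked, -0.29 within slide 1 (camera adjusted p = 0.00306, 0.216 with an estimated correlation, range 1.55e-05 to 0.216). Inflammatory genes had 5 falls, including Vcam1 (-1.29) and Lcn2 (-0.48), and 1 rise, Cxcl1 (1.45), among 15 (6 and 1 adjusted over the list alone). Their median was -0.17, or -0.18 blocked, -0.17 within slide 1 (camera adjusted p = 0.0312, 0.0869 with an estimated correlation, range 0.000775 to 0.126). The list lost its call with slide as a block and without DMSO replicate 1 or 2 or indomethacin replicate 3 (adjusted p up to 0.0663 on leaving out an array). Fatty acid and triglyceride synthesis had 3 falls among 20 (4 adjusted over the list alone), Thrsp at -1.10 ± 0.13 among them. The median was -0.13, or -0.20 blocked, -0.07 within slide 1 (camera adjusted p = 0.0278, 0.082 with an estimated correlation, range 0.00027 to 0.082). That call was lost without DMSO replicate 1 or indomethacin replicate 2 (adjusted p up to 0.0548).

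Median, mean and test differed in sign for 3 of the 11 lists that did not pass with indomethacin: Cdk5-linked genes, glycolysis and hypoxia, and oxidative stress and xenobiotic genes. Of the 66 called genes named for this drug, 62 were called with slide as a block and 50 whichever array was left out. The count of 1121 genes came to 1117 with the block and 1694 without the 2 arrays apart, and to 659 or 675 without DMSO replicate 1 or 2 and 521, 668 or 726 without indomethacin replicate 1, 2 or 3.

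Ibuprofen raised 467 genes and lowered 570. Acaa1b rose by 2.43 ± 0.16 (SE, n = 3 per group, adjusted p = 1.24e-09), with 2.47 blocked and 2.42 within slide 2, and Fgf21, Elovl3 and Krt23 by 2.34 ± 0.17, 2.10 ± 0.18 and 2.07 ± 0.17. Irs2 rose by 1.23 ± 0.15 and the stress transcription factor Ddit3 (CHOP) by 1.20 ± 0.18. Phkg1 changed by -1.52 ± 0.15 (adjusted p = 5.86e-07), with -1.75 blocked and -1.95 within slide 2.

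Among 23 PPARγ targets 8 rose with ibuprofen and 15 did not pass (8 rose adjusted over the list alone), with Angptl4 at 0.64 ± 0.12. The median was 0.27, or 0.29 blocked, 0.30 within slide 2 (camera adjusted p = 3.12e-06, 0.0017 with an estimated correlation, range 5.53e-09 to 0.0017). Cd36 at 0.71 lost its call without DMSO replicate 1 or 2 or ibuprofen replicate 1 or 2 (adjusted p up to 0.0947). Pdk4 at 0.53 did so without any array of DMSO replicates 1 and 3 or ibuprofen (up to 0.238). Fabp4 at 0.29 (adjusted p = 0.549) and Plin2 at 0.40 did not pass. Pparg fell by 0.40 (other probes -0.88 and -0.76), a call lost without DMSO replicate 1 or 3 or any ibuprofen array (adjusted p up to 0.143). In the fatty acid oxidation list 4 of 21 rose (7 adjusted over the list alone), such as Decr1 (0.93 ± 0.17). The median was 0.16, or 0.24 blocked, 0.22 within slide 2 (camera adjusted p = 0.00012, 0.0769 with an estimated correlation, range 2.77e-05 to 0.0769).

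Thermogenic genes were higher with ibuprofen, with 3 rises, Ppargc1a at 1.05 ± 0.17 among them, and 1 fall among 10 (the same numbers adjusted over the list alone). The median was 0.10, or 0.12 blocked, 0.15 within slide 2 (camera adjusted p = 0.0204, 0.0935 with an estimated correlation, range 0.000588 to 0.0935). Amino acid stress genes had 5 rises among 19 (7 adjusted over the list alone), with Ddit3 and the stress-induced Sesn2 (0.77 ± 0.18) among them. The median was 0.24, or 0.16 blocked, 0.21 within slide 2 (camera adjusted p = 0.00661, 0.0935 with an estimated correlation, range 0.000819 to 0.0935). That call was lost without DMSO replicate 3 (adjusted p = 0.0792). Extracellular matrix genes had 5 falls among 20 (11 fell and 1 rose adjusted over the list alone), with Lox at -1.15 ± 0.14. The median was -0.28, or -0.24 blocked, -0.16 within slide 2 (camera adjusted p = 0.000344, 0.0769 with an estimated correlation, range 4.38e-05 to 0.0769). Of 20 preadipocyte and fibroblast markers 7 fell (9 fell and 1 rose adjusted over the list alone), such as Tgfbi (-1.40 ± 0.17). The median was -0.34, or -0.31 blocked, -0.17 within slide 2 (camera adjusted p = 0.00141, 0.0935 with an estimated correlation, range 0.000153 to 0.0935). Inflammatory genes had 5 falls, Vcam1 at -0.93 ± 0.15 among them, and 1 rise, Cxcl1 at 0.96, among 15 (6 and 1 adjusted over the list alone). Their median was -0.22, or -0.17 blocked, -0.10 within slide 2 (camera adjusted p = 0.0158, 0.0769 with an estimated correlation, range 0.000588 to 0.0891). Interferon response genes had 2 falls among 15 (5 adjusted over the list alone). The median was -0.26, or -0.22 blocked, -0.28 within slide 2 (camera adjusted p = 0.0418, 0.414 with an estimated correlation, range 0.00578 to 0.414). Of its alternatives, 11 ended the call, among them leaving out DMSO replicate 3 or ibuprofen replicate 1 (adjusted p up to 0.167).

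The cell cycle list, with 1 rise among 19, came close to the threshold with ibuprofen (camera adjusted p = 0.0518), and median, mean and test differed in sign for Cdk5-linked genes, glycolysis and hypoxia, and ER chaperones. Of the 66 called genes named for ibuprofen, 43 were called with slide as a block and 37 whichever array was left out. The count of 1037 genes came to 380 with the block (134 higher, 246 lower) and 2340 without the 2 arrays apart, and to 416, 413 or 1562 without DMSO replicate 1, 2 or 3 and 540, 584 or 666 without ibuprofen replicate 1, 2 or 3. With arrays shifted to one median, 581 genes were higher and 472 lower.

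GQ16 raised 75 genes and lowered 82. Acaa1b rose by 1.38 ± 0.16 (SE, n = 3 per group, adjusted p = 0.000111), with 1.33 blocked and 1.15 within slide 2, and the secreted protein meteorin, Metrn, by 0.88 ± 0.15 (adjusted p = 0.00543). Lox changed by -1.02 ± 0.14 (adjusted p = 0.000999), with -0.95 blocked and -1.01 within slide 2, and Phkg1 by -1.02 ± 0.15 (adjusted p = 0.00143). These 4 were the only ones of the 27 called genes named for GQ16 that stayed called whichever array was left out.

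Elovl3 (0.89) and Irs2 (0.86) rose with GQ16, calls lost without DMSO replicate 1 or 2 (adjusted p up to 0.0714 and 0.0601), and Vcam1 (-0.77) fell, a call lost without DMSO replicate 1 or 2 or GQ16 replicate 2 (up to 0.0732). Of 23 PPARγ targets 1 rose and 22 did not pass (2 rose adjusted over the list alone), and the list did not pass by camera (median 0.06, 17 of 23 higher, adjusted p = 0.31) but was higher by fry (adjusted p = 0.0150). The called member was Fgf21 at 0.75, a call lost without DMSO replicate 1 or 2 or GQ16 replicate 2 or 3 (adjusted p up to 0.159). Fabp4 at 0.44, Cd36 at 0.18, Angptl4 at 0.30, Plin2 at 0.06 and Pparg at -0.28 (adjusted p = 0.229) did not pass. The cell cycle list was higher, with 1 rise among 19 (5 adjusted over the list alone). The median was 0.18, or 0.25 blocked, 0.42 within slide 2 (camera adjusted p = 0.00117, 0.206 with an estimated correlation, range 3.08e-05 to 0.206). Amino acid stress genes had 0 limma calls among 19 (5 higher and 0 lower at an unadjusted p under 0.05, 1 rise adjusted over the list alone). The median was 0.21, or 0.25 blocked, 0.34 within slide 2 (camera adjusted p = 0.00568, 0.177 with an estimated correlation, range 0.00192 to 0.177). That call was lost without DMSO replicate 3 or GQ16 replicate 2 (up to 0.098). Thermogenic genes had 1 rise among 10 (3 adjusted over the list alone). The median was 0.16, or 0.14 blocked, 0.01 within slide 2 (camera adjusted p = 0.0298, 0.177 with an estimated correlation, range 0.0128 to 0.309). It was no longer called with slide as a block and without DMSO replicate 1 or 2 or GQ16 replicate 2 (up to 0.209). The extracellular matrix list was lower, with 1 fall among 20 (4 fell and 1 rose adjusted over the list alone). The median was -0.17, or -0.15 blocked, -0.03 within slide 2 (camera adjusted p = 0.00464, 0.177 with an estimated correlation, range 0.00109 to 0.177).

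Preadipocyte markers (median -0.07, camera adjusted p = 0.318), fatty acid oxidation (0.08, 0.413) and inflammatory genes (0.00, 0.874) were among the 16 lists that did not pass with GQ16. Median, mean and test differed in sign for 7 lists: Cdk5-linked genes, fatty acid and triglyceride synthesis, cholesterol synthesis, glycolysis and hypoxia, inflammatory genes, the prostaglandin pathway and ribosomal proteins. Of the 27 called genes named for GQ16, 7 were called with slide as a block. Slide 2 set 1 GQ16 array against 1 DMSO array. The count of 157 genes came to 37 with the block (11 higher, 26 lower) and 681 without the 2 arrays apart. It came to 11 or 15 without DMSO replicate 1 or 2 and 256, 67 or 55 without GQ16 replicate 1, 2 or 3.

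**Figure D3:**
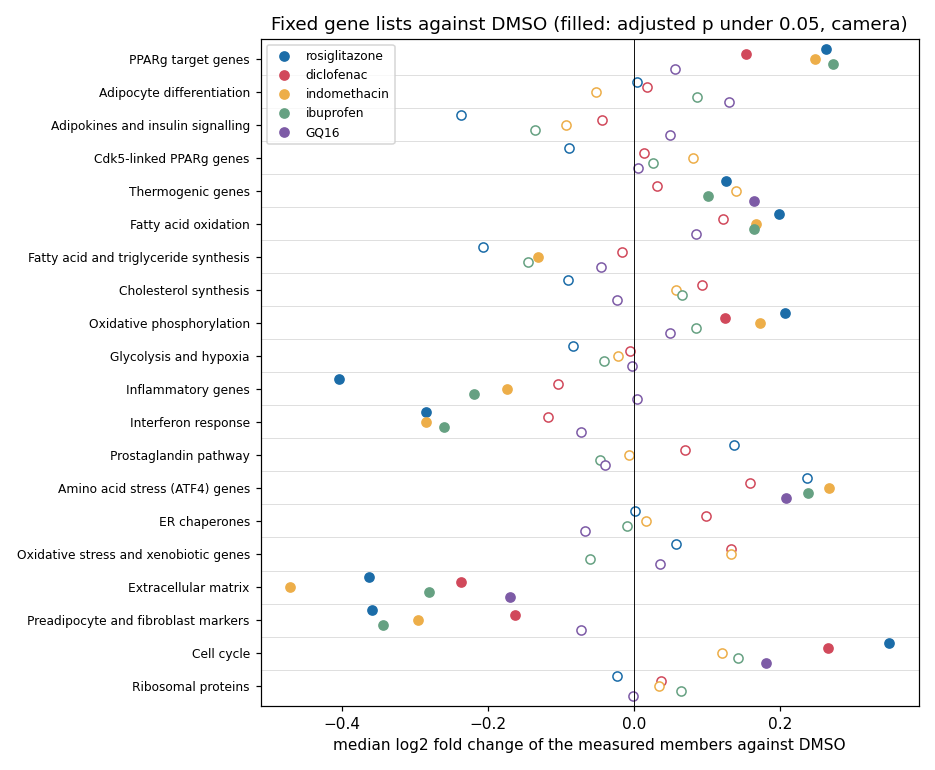
Median log2 fold change against DMSO of the measured members of 20 fixed gene lists, 1 point per compound, filled where the camera adjusted p was under 0.05 (medians over genes, no error bars). Extracellular matrix genes lie between -0.47 (indomethacin) and -0.17 (GQ16), and PPARγ targets between 0.06 (GQ16) and 0.27 (ibuprofen).

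Changes with the other compounds were next set against those with rosiglitazone across the 10958 genes. Pearson's r of the log2 changes was 0.77 for diclofenac, 0.83 for indomethacin, 0.76 for ibuprofen and 0.48 for GQ16, where unchanged groups simulated against the same DMSO arrays gave a mean of 0.50 (0.48 to 0.52). That simulation takes the arrays as independent; 100 regroupings of the arrays' residuals, added after the data had been seen, keep the structure between arrays and gave r of -0.27 to 0.84. With slide as a block r was 0.69, 0.75, 0.72 and 0.34. The covariance was 0.0624, 0.0911, 0.0833 and 0.0411 in the same order, against a simulated mean of 0.0120, a highest simulated value of 0.0128 and at most 0.0520 in the regroupings. Of the 1984 genes called for rosiglitazone, 97.2% changed in the same direction with diclofenac, 99.5% with indomethacin, 96.6% with ibuprofen and 81.1% with GQ16 (57.8% in the simulation, 61.5% at most, and up to 77.3% in the regroupings). Over these genes the median ratio of the change to that with rosiglitazone was 0.50, 0.71, 0.61 and 0.30. The genes were called from the rosiglitazone change that is also the divisor. That favours ratios under 1, so these values do not measure relative strength. Part of any excess may come from the shared controls.

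Genes called in the same direction as with rosiglitazone made up 95.2% of the calls for diclofenac, 81.1% for indomethacin, 66.9% for ibuprofen and 65.0% for GQ16. Leaving out an array moved these shares to 89.4 to 100%, 66.1 to 92.5%, 51.1 to 78.8% and 42.1 to 90.9%, and the order of the last 3 was not stable: without DMSO replicate 1 they stood at 82.5%, 78.1% and 90.9%. Rises shared with rosiglitazone numbered 60 for diclofenac (5.48 for independent lists), 302 for indomethacin (31.6), 276 for ibuprofen (37.6) and 54 for GQ16 (6.04). Shared falls numbered 159 (16.3), 607 (73.2), 418 (57.3) and 48 (8.24). Simulated unchanged groups and regroupings, here without a group effect, shared 0 limma calls. At an unadjusted p under 0.05 they shared up to 136 and 1188. With slide as a block the shared rises and falls came to 82 and 179 for diclofenac, 282 and 542 for indomethacin, 105 and 211 for ibuprofen, and 10 and 17 for GQ16. Leaving out an array gave 26 to 128 and 66 to 251 for diclofenac (without diclofenac replicate 2 and rosiglitazone replicate 1), 154 to 399 and 328 to 751 for indomethacin (indomethacin replicate 1 and rosiglitazone replicate 1), 108 to 469 and 208 to 559 for ibuprofen (lowest without DMSO replicate 2 or 1, highest without 3), and 4 to 101 and 6 to 100 for GQ16 (DMSO replicate 1 and rosiglitazone replicate 1). Acaa1b, Elovl3, Fgf21, Krt23 and Irs2 were among the 19 genes that rose with all 5 compounds, and Orm2, Lox, Vcam1, Phkg1 and Tgfbi among the 23 that fell with all 5 (Phkg1 was above background on 1 of 3 rosiglitazone arrays). These counts came to 6 and 7 with slide as a block, 66 and 89 without the 2 arrays apart, 2 and 4 without DMSO replicate 1, and 4 and 6 without DMSO replicate 2. They were 38 and 59 or 24 and 35 without rosiglitazone replicate 1 or 2, 11 and 16 or 13 and 15 without diclofenac replicate 1 or 2, 12 and 15 or 13 and 14 without indomethacin replicate 2 or 3, and 8 and 18 or 11 and 14 without GQ16 replicate 2 or 3.

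**Figure D4:**
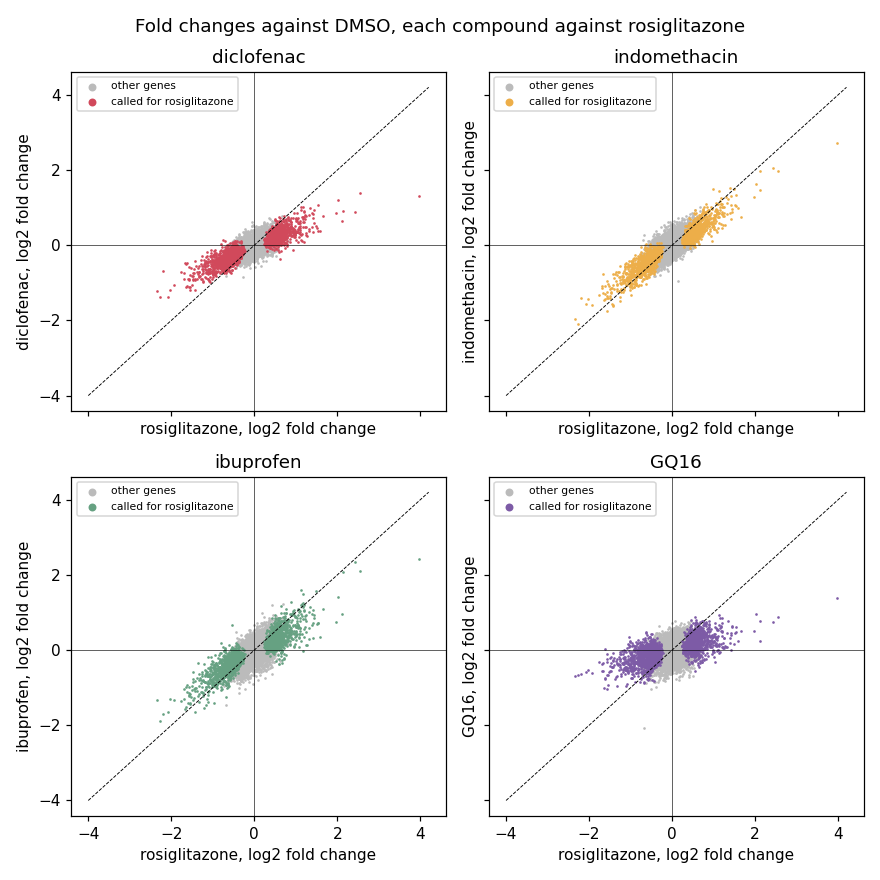
Log2 fold change against DMSO of 10958 genes with rosiglitazone (horizontal axis) and each other compound (vertical axis), with the 1984 genes called for rosiglitazone in colour and the dashed line marking equal changes (1 point per gene, no error bars). The coloured points lie mostly below the dashed line in size, with median ratios from 0.30 (GQ16) to 0.71 (indomethacin). Choosing the genes by their rosiglitazone change favours ratios under 1.

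Direct comparisons asked where compounds differed at the concentrations used, which were not matched. Diclofenac at 25 µM left Acaa1b lower than rosiglitazone at 100 nM did, by -2.65 (95% interval -2.99 to -2.32, adjusted p = 1.82e-10), with -2.63 blocked and -2.68 and -2.66 within slides 1 and 3. Fgf21 (-1.55, -1.90 to -1.19) and Krt23 (-1.21, -1.56 to -0.87) were lower too, and the G protein regulator Rgs2 (1.16, 0.76 to 1.56) and Orm2 (1.12, 0.83 to 1.41) were higher. In all, 111 genes were higher and 102 lower with diclofenac (85 and 131 with arrays shifted to one median). Camera called 5 lists higher and 3 lower. Lower were PPARγ targets (median -0.20, or -0.21 blocked, -0.20 and -0.12 within slides 1 and 3, camera adjusted p = 2.88e-05, 0.00361 with an estimated correlation, range 2.87e-07 to 0.00943). So were thermogenic genes (median -0.31, or -0.32 blocked, -0.30 and -0.38 within slides 1 and 3, camera adjusted p = 0.000623, 0.0374 with an estimated correlation, range 0.000152 to 0.0374). Extracellular matrix genes were higher (median 0.22, or 0.22 blocked, 0.22 and 0.15 within slides 1 and 3, camera adjusted p = 0.000507, 0.0808 with an estimated correlation, range 6.49e-05 to 0.0808), a call lost without rosiglitazone replicate 2 (adjusted p = 0.0761). Fatty acid oxidation was lower (median -0.16, -0.11 blocked, -0.23 and 0.05 within slides 1 and 3), and cholesterol synthesis (0.16, 0.19 blocked, 0.06 and 0.30 within slides 1 and 3), inflammatory genes (0.13, 0.11 blocked, 0.20 and 0.10 within slides 1 and 3), interferon response (0.24, 0.16 blocked, 0.08 and 0.39 within slides 1 and 3) and oxidative stress genes (0.02, 0.03 blocked, 0.10 and 0.07 within slides 1 and 3) were higher. Their adjusted p with an estimated correlation was 0.0808 to 0.303. All 5 lost their call without rosiglitazone replicate 2, all but the first without replicate 3, cholesterol synthesis, inflammatory and oxidative stress genes with slide as a block (adjusted p = 0.0983, 0.117 and 0.0695), and some without rosiglitazone replicate 1 or diclofenac replicate 1 or 3 (up to 0.397). Pparg did not pass at 0.41 (0.16 to 0.66, adjusted p = 0.0799). The count of 213 genes came to 439 with slide as a block (226 higher, 213 lower), and to 460 without rosiglitazone replicate 2 and 64, 80 or 104 without diclofenac replicate 1, 2 or 3.

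Between 10 µM indomethacin and 100 nM rosiglitazone 4 genes passed. Acaa1b at -1.24 (-1.58 to -0.91, adjusted p = 0.000347), the alcohol dehydrogenase Adh1 at -1.09 (-1.49 to -0.69) and the kinase Sgk2 at -0.74 (-0.94 to -0.54) were lower with indomethacin, and Ddit4 at 0.60 (0.38 to 0.81) was higher. For Acaa1b the change was -1.27 blocked and -1.20 and -1.29 within slides 1 and 3. Adh1 lost its call without rosiglitazone replicate 1 or 3 or any indomethacin array (adjusted p up to 0.185), and Ddit4 without rosiglitazone replicate 1 or any indomethacin array (up to 0.284). Genes that did not pass had wide intervals, such as Fgf21 (-0.38, -0.73 to -0.02, adjusted p = 0.563), Plin2 (0.14, -0.20 to 0.49) and Pparg (0.09, -0.16 to 0.34), so the low count does not show that these compounds act alike. At an unadjusted p under 0.05, 960 genes differed. Camera called 5 lists (4 at an unadjusted p under 0.05 and 0 after adjustment with an estimated correlation, 2 by fry). The cell cycle list was the lowest in p (median -0.22, or -0.15 blocked, -0.27 and -0.15 within slides 1 and 3, camera adjusted p = 0.00167, 0.211 with an estimated correlation, range 8.65e-08 to 0.211), a call lost without rosiglitazone replicate 3 (adjusted p = 0.126). PPARγ targets (median -0.03, -0.06 blocked, -0.08 and -0.06 within slides 1 and 3) and fatty acid oxidation (-0.10, -0.02 blocked, -0.11 and 0.02 within slides 1 and 3) were lower, and amino acid stress (0.05, 0.02 blocked, 0.14 and 0.05 within slides 1 and 3) and oxidative stress genes (0.13, 0.10 blocked, 0.07 and 0.20 within slides 1 and 3) higher, with an adjusted p of 0.0942 to 0.275 with an estimated correlation. All 4 lost their call with slide as a block and without rosiglitazone replicate 2 or 3 or indomethacin replicate 2 (up to 0.598). The count of 4 genes came to 15 with slide as a block, 126 without rosiglitazone replicate 2, and 2 without rosiglitazone replicate 1 or indomethacin replicate 1, 2 or 3.

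Ibuprofen at 75 µM and rosiglitazone at 100 nM shared no slide, so no within-slide value exists for them. Acot1, a cytosolic acyl-CoA thioesterase, was higher with ibuprofen by 1.20 (0.89 to 1.51, adjusted p = 5.55e-05), with 1.04 blocked, as were Orm2 (1.02, 0.74 to 1.31) and the protease Ctsl (0.93, 0.60 to 1.26). Acaa1b (-1.53, -1.87 to -1.20) and the immediate early factor Egr2 (-1.21, -1.62 to -0.79) were lower, and Fgf21 did not pass (-0.10, -0.45 to 0.26). PPARγ targets did not pass by camera (median -0.10, adjusted p = 0.233) but were lower by fry (0.0360). In all, 69 genes were higher and 78 lower. Oxidative phosphorylation was lower as a list (median -0.13, or -0.03 blocked, camera adjusted p = 0.00676, 0.299 with an estimated correlation, range 0.00104 to 0.338). Extracellular matrix genes were higher (median 0.17, or 0.14 blocked, camera adjusted p = 0.00665, 0.299 with an estimated correlation, range 0.00143 to 0.299). Both calls were lost with slide as a block and without rosiglitazone replicate 2 (adjusted p = 0.107 and 0.0959). The cell cycle list, the third called, was lower (median -0.32, -0.22 blocked, camera adjusted p = 0.0206, 0.393 with an estimated correlation, range 6.9e-06 to 0.401), and lost its call with the block and without rosiglitazone or ibuprofen replicate 3. The count of 147 genes came to 22 with the block, under which Ctsl and Egr2 were no longer called, and to 410 without the 2 arrays apart, 226 or 224 without rosiglitazone replicate 1 or 3 and 70, 34 or 59 without ibuprofen replicate 1, 2 or 3.

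Between 10 µM GQ16 and 100 nM rosiglitazone, 958 genes were higher and 662 lower with GQ16 (723 and 929 with arrays shifted to one median). Acaa1b (-2.58, -2.91 to -2.25, adjusted p = 3.3e-10), Cxcl1 (-1.88, -2.27 to -1.49), Fgf21 (-1.68, -2.04 to -1.33) and Elovl3 (-1.66, -2.02 to -1.30) were lower with GQ16, and Orm2 (1.64, 1.35 to 1.93) was higher. For Acaa1b the change was -2.58 blocked and -2.50 within slide 3. Pparg was higher by 0.48 (0.23 to 0.73, adjusted p = 0.00902), a call lost without GQ16 replicate 3 (adjusted p = 0.0601). Of 23 PPARγ targets 6 were lower with GQ16 (8 adjusted over the list alone). The median was -0.29, or -0.29 blocked, -0.22 within slide 3 (camera adjusted p = 1.25e-05, 0.0027 with an estimated correlation, range 3.74e-07 to 0.0027). Fatty acid oxidation was lower (median -0.20, or -0.26 blocked, -0.18 within slide 3, camera adjusted p = 0.00316, 0.143 with an estimated correlation, range 0.000162 to 0.143). Higher were inflammatory genes (median 0.36, or 0.35 blocked, 0.39 within slide 3, camera adjusted p = 0.0105, 0.0966 with an estimated correlation, range 0.000199 to 0.0966) and extracellular matrix genes (median 0.34, or 0.36 blocked, 0.26 within slide 3, camera adjusted p = 0.00203, 0.124 with an estimated correlation, range 0.00032 to 0.124). The other called lists were oxidative phosphorylation, lower (median -0.12, -0.11 blocked, -0.06 within slide 3), and, higher, preadipocyte markers (0.18, 0.23 blocked, 0.16 within slide 3), interferon response (0.22, 0.16 blocked, 0.26 within slide 3) and fatty acid and triglyceride synthesis (0.16, 0.18 blocked, 0.07 within slide 3), with an adjusted p of 0.124 to 0.381 with an estimated correlation. All 4 lost their call without rosiglitazone replicate 2, the last 2 and the first also with slide as a block and without rosiglitazone replicate 3 or GQ16 replicate 3, and the last 2 without GQ16 replicate 2, the last also without replicate 1 (up to 0.142). The count of 1620 genes came to 1986 with slide as a block.

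Among the anti-inflammatory drugs, 25 µM diclofenac and 10 µM indomethacin differed at 20 genes (6 higher, 14 lower with diclofenac, 4 and 17 with arrays shifted to one median). Acaa1b (-1.41, -1.74 to -1.07, adjusted p = 7.79e-05) and Fgf21 (-1.17, -1.53 to -0.81) were lower with diclofenac (for Acaa1b, -1.36 blocked and -1.48 and -1.37 within slides 1 and 3). Camera called 7 lists (0 after adjustment and 5 at an unadjusted p under 0.05 with an estimated correlation, 2 by fry). Extracellular matrix genes were higher with diclofenac, with 0 limma calls among 20 (8 higher and 0 lower at an unadjusted p under 0.05, 4 higher adjusted over the list alone). The median was 0.23, or 0.22 blocked, 0.20 and 0.24 within slides 1 and 3 (camera adjusted p = 1.65e-05, 0.0592 with an estimated correlation, range 1.2e-06 to 0.0592). Interferon response (median 0.17, 0.26 blocked, 0.07 and 0.37 within slides 1 and 3) and cell cycle genes (0.23, 0.20 blocked, 0.18 and 0.22 within slides 1 and 3) were higher too, and PPARγ targets (-0.04, -0.08 blocked, -0.04 and -0.10 within slides 1 and 3), thermogenic genes (-0.12, -0.08 blocked, -0.18 and -0.10 within slides 1 and 3), fatty acid oxidation (-0.11, -0.12 blocked, -0.11 and 0.01 within slides 1 and 3) and amino acid stress genes (-0.09, -0.06 blocked, -0.06 and -0.15 within slides 1 and 3) lower. Their adjusted p with an estimated correlation was 0.0592 to 0.284. All 6 lost their call without diclofenac replicate 3, and some without diclofenac replicate 2 or indomethacin replicate 1, 2 or 3 (up to 0.468). The count of 20 came to 24 with slide as a block, 108 without the 2 arrays apart, and 5, 5 or 8 without diclofenac replicate 1, 2 or 3 and 6, 7 or 6 without indomethacin replicate 1, 2 or 3.

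Against 75 µM ibuprofen, diclofenac left 37 genes higher and 58 lower (35 and 95 with arrays shifted to one median). Fgf21 (-1.45, -1.80 to -1.09, adjusted p = 0.000153), Krt23 (-1.16, -1.50 to -0.81) and Acaa1b (-1.12, -1.45 to -0.79) were lower with diclofenac, and for Fgf21 the change was -1.42 blocked and -1.58 within slide 2. Camera called 3 lists, all lower with diclofenac: PPARγ targets (median -0.13, or -0.16 blocked, -0.17 within slide 2, camera adjusted p = 0.0124, 0.0983 with an estimated correlation, range 0.000702 to 0.0983), a call lost without diclofenac replicate 3 (adjusted p = 0.0976), thermogenic genes (median -0.18, or -0.19 blocked, -0.15 within slide 2, camera adjusted p = 0.0124, 0.123 with an estimated correlation, range 0.00466 to 0.123) and fatty acid oxidation (median -0.13, or -0.14 blocked, -0.11 within slide 2, camera adjusted p = 0.0124, 0.198 with an estimated correlation, range 0.00342 to 0.198). The count of 95 came to 17 with slide as a block, 702 without the 2 arrays apart, and 20, 11 or 44 without diclofenac replicate 1, 2 or 3 and 28, 12 or 26 without ibuprofen replicate 1, 2 or 3.

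Indomethacin and ibuprofen, which shared no slide, differed at 29 genes, with 18 higher and 11 lower with indomethacin (13 and 5 with cyclic loess). The immediate early factors Egr2 (1.29, 0.87 to 1.70, adjusted p = 0.00677) and Egr1 (1.19, 0.75 to 1.62) were higher with indomethacin and Acot1 lower (-0.99, -1.30 to -0.68); with slide as a block they stood at 1.27, 1.02 and -0.84 and were not called. Egr2 and Acot1 lost their calls without ibuprofen replicate 2 or indomethacin replicate 1 or 3 (adjusted p up to 0.106 and 0.106), and Egr1 without any array of either drug except ibuprofen replicate 1 (up to 0.106). Fgf21 (-0.28, -0.63 to 0.08) and Pparg (-0.27, -0.52 to -0.03) did not pass. Extracellular matrix genes were lower with indomethacin as a list (median -0.21, or -0.13 blocked, camera adjusted p = 0.0115, 0.4 with an estimated correlation, range 0.000872 to 0.4), and oxidative phosphorylation higher (median 0.13, or 0.07 blocked, camera adjusted p = 0.0204, 0.4 with an estimated correlation, range 0.00399 to 0.4). Both calls were lost with slide as a block, and the second without ibuprofen replicate 1 or 2 or indomethacin replicate 1 (up to 0.0891). The count of 29 came to 0 by limma with the block (1212 at an unadjusted p under 0.05), 831 without the 2 arrays apart, 3 without indomethacin replicate 2, 5 or 2 without ibuprofen replicate 1 or 3, and 0 by limma without indomethacin replicate 1 or 3 or ibuprofen replicate 2, where 1157, 1494 and 1327 had an unadjusted p under 0.05.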

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

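The tests of shared DMSO arrays and of a wrong label, the comparisons with regrouped residuals and the blocked ratios for ibuprofen were chosen only after the result was seen.

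Probes without a single gene symbol entered none of the comparisons, yet many differed from DMSO. Among 3458 such probes above background, limma called 296 higher after rosiglitazone, 18 after diclofenac, 113 after indomethacin, 128 after ibuprofen and 10 after GQ16. Lower were 280, 42, 108, 118 and 12 in the same order.

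Changes with GQ16 and rosiglitazone covaried, at 0.0411 against at most 0.0128 for unchanged groups simulated with independent arrays, but 100 regroupings of the arrays' residuals, which keep the structure between arrays, reached 0.0520. Shared DMSO arrays stay open: the change from DMSO to GQ16 correlated at 0.181, 0.306 and 0.0595 with rosiglitazone minus diclofenac, indomethacin and ibuprofen, which share no array with it, the change from DMSO to rosiglitazone at -0.280, -0.451 and -0.433 with GQ16 minus the same drugs, and regroupings ranged from -0.650 to 0.613. Slide stays open too: with slide as a block the covariance was 0.0286, above the highest blocked simulation of 0.0129 that had been set as deciding, but that bound took arrays as independent, and blocked regroupings reached 0.0509. Of the 1984 genes called for rosiglitazone, 81.1% moved the same way with GQ16, against at most 77.3% in the regroupings. The DMSO arrays helped call the genes, so this cannot decide. Nor can the 54 rises and 48 falls shared: regroupings without a group effect had little scope for shared limma calls (0). The shared calls fell to 4 and 6 without DMSO replicate 1. A weaker response of the same kind as to rosiglitazone may account for the pattern, as a hypothesis that these tests did not separate from either.

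Rosiglitazone replicate 1 stood apart from the other rosiglitazone arrays, with 263 genes differing by over 1 on the log2 scale. A DMSO sample under the wrong label was argued against, since 90.3% of the 1701 genes called without this array lay on the called side of the DMSO mean on it, with a median ratio of 0.85 to the change without it. By the bounds of 0.05 set beforehand the preadipocyte and adipocyte lists (medians 0.0146 and 0.0134) went against a less differentiated culture. It stays open for reasons added later. Members spread more (13 of 20 and 9 of 18 higher, SD 0.368 and 0.415). Medians lay below 0 for fatty acid oxidation (-0.259, 7 of 21 higher) and adipokines and insulin signalling (-0.217, 5 of 15). Slide stays open, because the array's root mean square residual of 0.189 with slide as a block (0.286 before) was still the highest of the 18 arrays, but close to the 0.181 of rosiglitazone replicate 2. Sample quality, which could move several arrays along 1 axis, stays open too: the array's deviation correlated at 0.258 with the first residual component of the 15 arrays of other groups, under the 0.3 set as deciding, and no other biological explanation was tested.

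All 3 ibuprofen arrays lay on slide 2, which held 1 of the 3 DMSO arrays. Over the 1037 called genes the slide 2 change had a median ratio of 0.802 to that over all arrays, and 99.8% kept their sign. That rests on 1 DMSO array. With slide as a block the ratio was 0.889 (scaled median absolute deviation 0.187), and 1.01 (0.313) without that array. Calling the genes from the same arrays favours these values. Genes still called with the block, though fewer, go against slide as the whole cause. Against the 2 DMSO arrays of slide 1 the median ratio was 1.10, so slide may add to the size of single changes, which stays open. A response to ibuprofen remains the hypothesis for the rest.

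Of 100 drawn splits of the 18 arrays into 6 groups, 1, the real one, gave as many genes in the F test (2026, highest other 32). Chance is thus unlikely if arrays are independent. For 3 arrays against 3, 10 splits are too few for a share under 0.05, and each time only the real one gave as many. Against DMSO the real count and the highest other were 1984 and 255 for rosiglitazone, 230 and 0 for diclofenac, 1121 and 0 for indomethacin, 1037 and 0 for ibuprofen, and 157 and 38 for GQ16. Against rosiglitazone they were 213 and 0 for diclofenac, 4 and 0 for indomethacin, 147 and 8 for ibuprofen, and 1620 and 143 for GQ16. Between the anti-inflammatory drugs they were 20 and 0 for diclofenac and indomethacin, 95 and 0 for diclofenac and ibuprofen, and 29 and 0 for indomethacin and ibuprofen. Where limma called 0, the highest other counts at an unadjusted p under 0.05 were, in this order, 1072, 722, 1669, 1799, 1681, 229, 711 and 308. For diclofenac and indomethacin against rosiglitazone the real splits gave fewer at that level, 1705 and 960. The split with 255 genes set DMSO replicates 1 and 2 and rosiglitazone replicate 2, all on slide 1, against the rest; with slide as a block the real split gave 1959.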

How the results depend on the processing

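The stricter filter, the shift to one median, cyclic loess, gene-by-gene array weights and the fit without the 2 arrays that stood apart were chosen only after the data had been seen; the other alternatives were planned. Of the values of named genes under the alternatives, 0 of 6730 changed sign where either fit called the gene and 108 of 1818 did where neither did; 7445 kept their side of the threshold, 1041 lost their call and 62 gained one. For lists, 1203 kept their call and 217 lost it. Counts of genes or lists stayed within 1.5 times in 224 cases and moved further in 148. The causes of these moves were not tested. The planned runs without background correction and with a median shift after it were not run, because the non-normalized signals could not be matched to samples; for the same reason the filter on detection p-values was replaced. Probes near the floor of the deposited values are compressed, which limits what can be said of dim genes.

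The stricter filter, the shift to one median and the replicate block moved no count of genes or lists, and no correlation, past those limits. With the replicate number as a block, 1991 genes differed among the groups, and the counts against DMSO were 1928 for rosiglitazone, 201, 1078 and 1017 for diclofenac, indomethacin and ibuprofen, and 137 for GQ16. The numbers do not pair the arrays: deviations of same-numbered arrays correlated at -0.33 to 0.53 (mean -0.00542), 10 of 45 pairs above 0.1, and 7 of 18 arrays correlated best with their own number.

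Without a filter, counts were 685 for ibuprofen and 96 for GQ16 against DMSO, 108, 2 and 70 for diclofenac, indomethacin and ibuprofen against rosiglitazone, and 7, 31 and 5 for diclofenac with indomethacin, diclofenac with ibuprofen and indomethacin with ibuprofen. Counted in probes, they were 3775 among the groups, 3578, 1804 and 2092 for rosiglitazone, indomethacin and ibuprofen against DMSO, 328 and 2849 for diclofenac and GQ16 against rosiglitazone, and 32 and 219 for diclofenac with indomethacin and ibuprofen. With no intensity trend indomethacin and ibuprofen differed at 50 genes, and with cyclic loess at 18.

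With slide as a fixed block, ibuprofen had 380 genes and GQ16 37 genes and 7 lists. Against rosiglitazone the counts were 439, 15 and 22 for diclofenac, indomethacin and ibuprofen, diclofenac and ibuprofen differed at 17 genes, and indomethacin and ibuprofen at 0 by limma (1212 at an unadjusted p under 0.05). Correlations with rosiglitazone were 0.69, 0.75, 0.72 and 0.34 for diclofenac, indomethacin, ibuprofen and GQ16. Slide as a random block (correlation 0.0919) gave 87 for GQ16, 85 for ibuprofen against rosiglitazone and 10 for indomethacin with ibuprofen. On slide 1 alone, counts were 61 for diclofenac, 488 for indomethacin, 14 for diclofenac against rosiglitazone, and 0 by limma for indomethacin against rosiglitazone (403 unadjusted) and against diclofenac (595). Slide 2, with 1 DMSO array, gave 5 for diclofenac, 150 for ibuprofen, and 0 by limma for GQ16 (1380) and for diclofenac with ibuprofen (1312). Slide 3, where rosiglitazone replicate 1 was the only rosiglitazone array, gave 439 and 1057 for indomethacin and GQ16 against rosiglitazone, and 0 by limma for diclofenac against rosiglitazone (2177) and indomethacin (503).

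Limma's default array weights did not converge, and the gene-by-gene method was added after their counts had been seen. The default gave 6986 genes among the groups, 5897, 1861, 4358, 3614 and 708 for rosiglitazone, diclofenac, indomethacin, ibuprofen and GQ16 against DMSO, 2263, 2476 and 1443 for the 3 anti-inflammatory drugs in the same order against rosiglitazone, 600, 989 and 1695 for diclofenac with indomethacin, diclofenac with ibuprofen and indomethacin with ibuprofen, and correlations of 0.82 for ibuprofen and 0.58 for GQ16. Gene by gene the values were 5309 among the groups, 3877, 1677, 4097, 3442 and 603 against DMSO, 595, 76 and 341 against rosiglitazone, 593, 1007 and 1681 among the drugs, and correlations of 0.82, 0.81 and 0.56 for diclofenac, ibuprofen and GQ16. Without rosiglitazone replicate 1 and DMSO replicate 3 they were 3522 among the groups, 487, 1694, 2340 and 681 for diclofenac, indomethacin, ibuprofen and GQ16, 410 for ibuprofen against rosiglitazone, 108, 702 and 831 among the drugs, and correlations of 0.84 and 0.92 for diclofenac and indomethacin.

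With only the 2 groups compared in the fit, counts were 745, 1888 and 3 for rosiglitazone, indomethacin and GQ16 against DMSO, 31, 1, 15 and 314 for diclofenac, indomethacin, ibuprofen and GQ16 against rosiglitazone, and 490, 812 and 1631 among the drugs. With an estimated correlation camera called 2, 2, 2 and 1 lists for rosiglitazone, diclofenac, indomethacin and ibuprofen, and 0 for GQ16 (4 at an unadjusted p under 0.05); fry called 14 for rosiglitazone and 9 for diclofenac. Spearman correlations with rosiglitazone were 0.71, 0.77 and 0.70 for the 3 drugs, and over genes called for rosiglitazone Pearson's r was 0.91, 0.95, 0.91 and 0.71 with GQ16 last.

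Each array was left out in turn, and where that left 2 arrays in a group the pooled spread of all groups was used. Counts ranged from 1415 to 2837 among the groups, 1198 to 2417 for rosiglitazone, 93 to 229 for diclofenac, 521 to 1121 for indomethacin, 413 to 1562 for ibuprofen and 11 to 256 for GQ16. Against rosiglitazone they ranged from 64 to 460 for diclofenac, 2 to 126 for indomethacin, 34 to 226 for ibuprofen and 1086 to 1652 for GQ16. Diclofenac and indomethacin differed at 5 to 8 genes, diclofenac and ibuprofen at 11 to 44, and indomethacin and ibuprofen at 0 to 5, with 0 by limma without ibuprofen replicate 2 (1327 at an unadjusted p under 0.05) or indomethacin replicate 1 (1157) or 3 (1494). Lists numbered 9 to 10, 5 to 6, 7 to 10, 6 to 10 and 2 to 4 for rosiglitazone, diclofenac, indomethacin, ibuprofen and GQ16, and correlations lay at 0.68 to 0.82, 0.70 to 0.91, 0.70 to 0.81 and 0.40 to 0.58 for the last 4.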

Other observations

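The gene groups described here were chosen only after their values were seen. Besides those already named, the genes that rose with all 5 included Hcar2, a niacin receptor (1.21, 0.89, 1.02, 1.07 and 0.50 on the log2 scale for rosiglitazone, diclofenac, indomethacin, ibuprofen and GQ16) and the peroxisome assembly gene Pex16 (0.88, 0.73, 0.81, 0.95 and 0.67). Genes that fell with all 5 included the matrix protein Sparcl1 (above background on 2 of 3 rosiglitazone arrays; -1.56, -0.90, -1.36, -1.20 and -0.65) and the p53 relative Trp63 (-1.48, -0.89, -1.14, -1.33 and -0.55). Of the genes that rose with any compound, 702 did so with 1, 278 with 2, 132 with 3, 34 with 4 and 19 with all 5; of those that fell, 655, 371, 228, 112 and 23 did. The counts for all 5 were 2 and 4 or 4 and 6 without DMSO replicate 1 or 2, and 6 and 7 with slide as a block. A gene called with 1 compound is not shown to differ from the others by that.

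Some genes changed further from DMSO than with rosiglitazone, or the other way, with both comparisons past the threshold. Ibuprofen had 13 of these. Acot1 stood at 0.67 with ibuprofen and -0.54 with rosiglitazone (direct difference 1.20, adjusted p = 5.55e-05) and Ddit3 at 1.20 and 0.44 (0.76, adjusted p = 0.0332). GQ16 had 29, of which 21 were lower, among them Gulp1, an adaptor for engulfment (-0.76 with GQ16, 0.10 with rosiglitazone, difference -0.86, adjusted p = 0.000406) and the ubiquitin ligase subunit Fbxl5 (-0.79, 0.16, -0.95, adjusted p = 0.00172). The 29 came to 10 with slide as a block, 1 without DMSO replicate 1, 0 by limma without DMSO replicate 2 (394 at an unadjusted p under 0.05 in both comparisons), 97 without rosiglitazone replicate 1 and 137 without both it and DMSO replicate 3. The 13 came to 0 by limma with the block (166), 1 without ibuprofen replicate 2, 42 without DMSO replicate 3, 36 without rosiglitazone replicate 1 and 128 without these last 2 arrays. Genes past the threshold in both comparisons that changed less than with rosiglitazone numbered 26 with ibuprofen, 29 with GQ16, 37 with diclofenac and 3 with indomethacin.

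Other probes of the named, called genes went the opposite way for 6 of 51, 1 of 13, 7 of 41, 5 of 41 and 5 of 21 with rosiglitazone, diclofenac, indomethacin, ibuprofen and GQ16.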
